A study of Mus musculus with 32 samples.

How the data were processed

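Mouse NIH 3T3 fibroblasts were transfected with a plasmid carrying FoxO6 joined to EGFP or with an empty vector, and confluent cultures were treated with 30 µM forskolin to set their circadian clocks in step. Medium held 10% serum and RNA was taken with Trizol at 24, 30, 36 and 42 h after forskolin, per the labels' protocols. Each of the 32 arrays compared 1 sample with a common reference, a pool of cRNA from NIH 3T3 cells that had not been synchronized. The labels put the samples into 8 groups of 4, replicates a to d, by plasmid and time. In every group 2 samples carried Cy5 and 2 carried Cy3, with the reference in the opposite dye. The series text says that the experiment was done 4 times, but not whether the repeats were separate cultures, so p-values measure the spread between these samples, which may be partly technical.

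The array files hold the intensity of each spot and of its local background in both channels on a linear scale, per the file headers, with no normalization applied. The labels name Cy5 for channel 1 and Cy3 for channel 2. Scanner, software and settings are not given in the sources used here. The series table holds log2 ratios as the authors deposited them, with scale, centring and direction unstated. Set against 5586 brighter spots of each array, its columns followed log2 sample over reference with slopes of 0.887 to 0.992 and correlations of 0.95 to 0.986 across spots, on arrays of either dye orientation. Column medians lay between -0.0148 and 0.0112, so the columns were close to centred on 0, while the background treatment and normalization behind them stayed unknown. The series table entered only as an alternative.

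Each array had 45220 spots, of which 4046 were controls. Of the 41174 measured probes, 34186 had 1 gene symbol in the platform annotation, 0 had several and 6988 had none; that annotation gives symbols only and can be old, so some symbols have since changed. Spot means were corrected against the local background median with normexp (offset 50) and normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. The log2 ratio was then turned to sample over reference on every array, and spots of a probe were averaged. A spot counted as above background where its mean exceeded the local background median by 2 SD. A probe was kept if this held in the sample channel on at least 4 of 32 arrays, which left 38921 probes. For each symbol the probe with the highest mean intensity over all arrays stood for the gene, and probes without a symbol were tested singly. This gave 24308 tests, 17996 with a symbol and 6312 without, and other probes were compared with it for named genes. Of 132 named genes with several probes, at least 1 probe differed from the brightest in its call for 58 in the mean difference between vectors and for 38 over time, and only some of these are given.

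limma fitted group means and a dye term to all 32 arrays, with 1 estimate of spread per gene, followed by eBayes. Contrasts were FoxO6 minus empty vector as the mean over 4 times and at each time. F-tests covered the interaction of vector and time, and time within each vector. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a contrast. Of 25 lists, 24 were tested; the FoxO family, with 4 members, is given as values. The other lists covered the core clock, clock-controlled output, FoxO targets, PI3K and insulin signalling, DNA replication, mitosis, cell cycle inhibitors with p53 targets, interferon, NF-kB, immediate early genes, unfolded protein and integrated stress, heat shock and oxidative stress, cholesterol and fatty acid synthesis, autophagy, glycolysis, the respiratory chain, extracellular matrix, contractile genes, mesenchymal identity, and adipocyte, myogenic, macrophage, epithelial with endothelial, and neural markers.

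Designs, lists and the choice of named genes were fixed before the data were examined. Named were the FoxO family, every core clock gene kept, the 12 rising and 12 falling genes with the largest mean change past the threshold and 1 sign at all 4 times, the 3 rising and 3 falling at each time, up to 6 for the interaction, the 12 with the widest range over time in empty vector cells, and up to 4 members per list with the smallest p. For clock genes over time, the p is that of the F-test unless a pair of times is named. Other names are said to have been chosen after their values were seen.

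The fits were tested on simulated data, with changes added to 50 genes per size among 24308. At a log2 change of 0.2 the mean contrast recovered 72% of them, and at 0.3 it recovered 90%. Comparisons at a single time recovered 32% to 40% at 0.2 and 76% to 82% at 0.5. The interaction recovered 34% at 0.2 and 72% at 0.5. False calls were 12 of 226 for the mean contrast and 6 of 130 for the interaction. For the vector contrasts the 39 measured mitosis genes were shifted by 0.3 as well. Changes for the interaction were placed in empty vector samples at 36 and 42 h. Noise was drawn independently for each gene, so false calls under correlation between genes were not tested. The number of arrays limits precision, and dim probes limit the size of a ratio that can be seen.

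Alternatives were no background correction, median centring in place of loess, quantile scaling of mean intensities between arrays, no filter and a filter at 16 arrays, no dye term, the replicate letter as a block, every probe on its own, fits on fewer arrays, the series table, array weights, and leaving out each array. Leaving out each time, or the pair of arrays with the largest residuals (empty vector 24 h c and 36 h c), was added after the data were seen. A batch of slides or scans was not run, since the files used here name none.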

Results

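Expression was measured on 2-colour Agilent mouse arrays in NIH 3T3 cells, an immortalized mouse embryonic fibroblast line, that carried FoxO6 or an empty vector. FoxO6 is a forkhead transcription factor of the FoxO family. The series title places the comparison in work on FoxO factors and the circadian clock gene Clock. Each vector was sampled at 24, 30, 36 and 42 h after forskolin, with 4 arrays per group and 16 per vector. Between 86.0% and 93.4% of probes lay above background in samples labelled with Cy5, and between 79.1% and 88.2% in those labelled with Cy3. Median sample signals were 107.9 to 142.5 in Cy5 and 68.1 to 84.5 in Cy3. Arrays of 1 dye orientation correlated at 0.599 to 0.837 in Cy5 and 0.581 to 0.833 in Cy3 across probes. All values are log2 ratios to the common reference, and differences between groups are given with their SE from limma.

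The probe for Foxo6 was not higher in samples labelled FoxO6. Its mean difference was -0.03 (SE 0.05, n = 16 per vector, limma adjusted p = 0.759), and it lay above background on all 32 arrays. The other family members gave no difference past the threshold either, with 0.01 for Foxo1, -0.02 for Foxo3 and -0.02 for Foxo4. In empty vector cells at 24 h Foxo6 stood at -0.20 ± 0.24 (SD, n = 4), and in samples labelled FoxO6 at -0.22 ± 0.13 (SD, n = 4). Where this probe lies relative to the sequence on the plasmid is not given in the sources used here, so it checks no label.

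Averaged over the 4 times, Retnla, a secreted resistin-like protein, rose most in samples labelled FoxO6, by 0.97 (SE 0.04, 1.96-fold, adjusted p = 1.76e-14, n = 16 per vector). At 24 h it stood at 1.40 ± 0.11 against 0.15 ± 0.03 in empty vector cells (SD, n = 4 each), and its other probe rose by 0.84. Rrm2, the small subunit of ribonucleotide reductase, rose by 0.64 (SE 0.06, 1.56-fold, adjusted p = 9.91e-08). Nrm, a protein of the inner nuclear membrane, fell by 0.59 (SE 0.04, adjusted p = 2.05e-09), although its other probe gave -0.03. Npc2, a lysosomal cholesterol carrier, fell by 0.55 (SE 0.10, adjusted p = 3.13e-04). Lcn2, an iron-binding acute phase protein, fell by 0.55 (SE 0.08, adjusted p = 1.7e-05).

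Further genes that rose were Exo1, a DNA exonuclease, by 0.52, Hmga2, a chromatin protein, by 0.51, and the chemokine gene Ppbp by 0.51. Tfrc, the transferrin receptor, rose by 0.50, Shcbp1 by 0.50, Zfhx3 by 0.49, Ptgs2, the inducible cyclooxygenase, by 0.49, and Uhrf1, which helps to maintain DNA methylation, by 0.49. The mitotic kinase gene Pbk rose by 0.48 and the kinesin gene Kif15 by 0.48, while the dimmer probe of Kif15 gave -0.01. Complement C3 fell by 0.54, with -0.04 at 24 h and -1.19 at 42 h. Sdk2 fell by 0.54 on its brightest probe, whereas its 3 dimmer probes gave -0.00, 0.01 and 0.02. Txnip, an inhibitor of thioredoxin, fell by 0.51, Ly6a by 0.50, the isocitrate dehydrogenase gene Idh1 by 0.50, Saa3 by 0.49, Igf2 by 0.48, Hspb9 by 0.48 and the chemokine gene Ccl5 by 0.45. SEs of these genes lay between 0.04 and 0.13. Without a dye term, Idh1 (adjusted p = 0.0512), Npc2 (adjusted p = 0.0564) and Igf2 (adjusted p = 0.365) no longer passed.

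**Figure D1:**
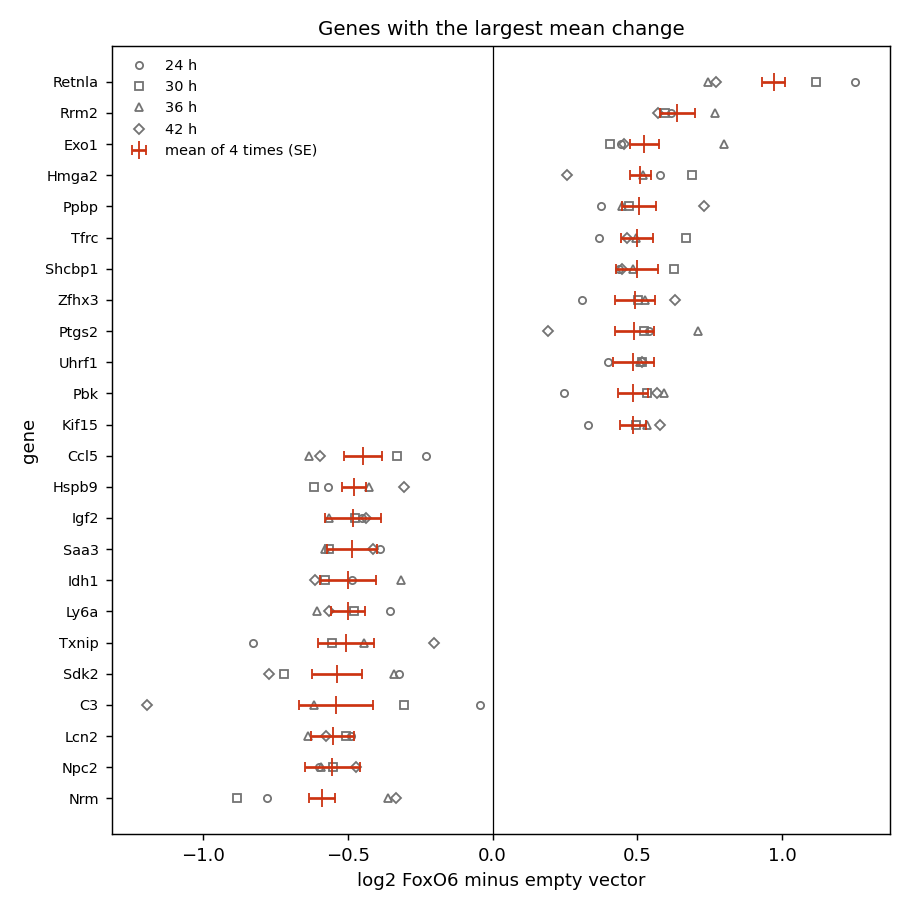
Mean log2 difference of samples labelled FoxO6 minus empty vector for the 12 rising and 12 falling genes, as red ticks with SE bars, and the difference at each of the 4 times as open symbols. Retnla lies at 0.97 and Nrm at -0.59, and all 4 times of each gene lie on 1 side of 0, which the rule for naming them required.

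In total 2554 of 24308 tests passed for the mean over times, 1491 higher and 1063 lower in samples labelled FoxO6, and 5532 had an unadjusted p under 0.05. The median absolute change among them was 0.17, and 4 exceeded 1.5-fold. Of the 2554, 2356 had 1 sign at all 4 times, which selection on the mean of these times favours. With median centring in place of loess 1086 passed, 473 higher and 613 lower, so the share that was higher went from 58.4% to 43.6%. Without a dye term 1395 passed.

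Genes of DNA replication rose together. Of 39 measured members, 29 rose, 0 fell and 10 did not pass, and adjusted over the list alone 32 rose. Tk1, thymidine kinase, rose by 0.32 (SE 0.02, adjusted p = 1.3e-09), Cdc6, which loads the replicative helicase, by 0.27 (SE 0.02, adjusted p = 2.05e-08), and Pole, a DNA polymerase, by 0.30 (SE 0.04, adjusted p = 2.53e-06). The list had a median change of 0.27 and an adjusted p of 4.37e-30, or adjusted p = 1.75e-06 with an estimated correlation. Its mean over members stood at 0.02 ± 0.08 in empty vector cells and 0.24 ± 0.05 in samples labelled FoxO6 at 24 h, and at -0.42 ± 0.03 against -0.22 ± 0.02 at 42 h (SD, n = 4 each).

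Genes of mitosis rose as well, with 31 of 39 measured members higher, 0 lower and 8 not past the threshold, and 32 higher when adjusted over the list alone. Examples were Plk1 at 0.33 (SE 0.04, adjusted p = 4.71e-06) and Ttk at 0.18 (SE 0.02, adjusted p = 7.35e-07), both mitotic kinases, and the spindle kinesin Kif11 at 0.24 (SE 0.03, adjusted p = 1.81e-05). The list median was 0.30 with an adjusted p of 9.3e-33, or adjusted p = 3.78e-09 with an estimated correlation. At 42 h the mean over members was -0.53 ± 0.03 in empty vector cells and -0.20 ± 0.02 in samples labelled FoxO6 (SD, n = 4 each). From 24 to 42 h the median change of mitosis genes was -0.70 in empty vector cells and -0.48 with FoxO6, and that of replication genes -0.47 and -0.48. At 24 h the mitosis means had been 0.13 ± 0.03 and 0.27 ± 0.01 (SD, n = 4 each), so this list fell less with FoxO6, beyond the spread between arrays. Of either list 0 members passed the interaction adjusted over the list alone. Adjusted over all genes, the interaction test recovered only 34% of simulated changes of 0.2. Recovery adjusted over a list alone was not simulated, and no list was tested for interaction as a whole. Top2a, a topoisomerase in the mitosis list, has a further probe that passed in the opposite direction.

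**Figure D2:**
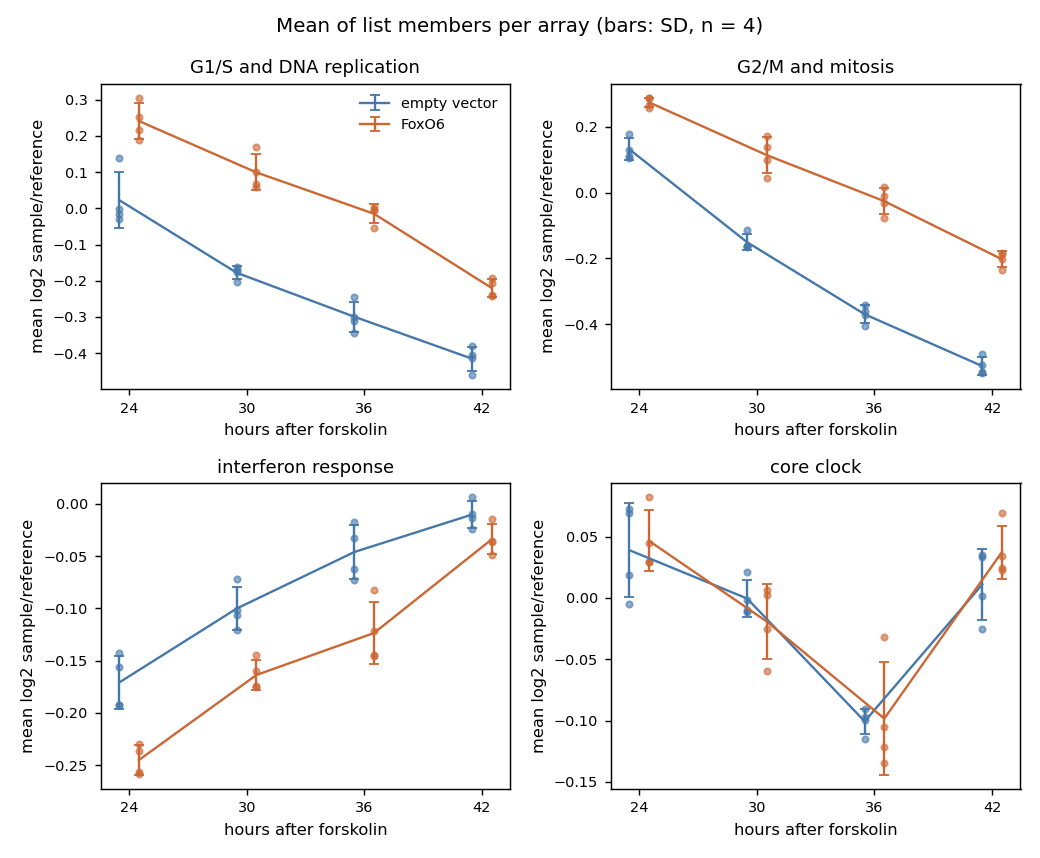
Mean log2 sample over reference of the members of 4 gene lists on each array, against hours after forskolin, for empty vector (blue) and FoxO6 (orange); points are arrays, lines join group means and bars are SD (n = 4). The replication and mitosis lists lie higher and the interferon list lower with FoxO6 at each time, while the core clock lines overlap.

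Interferon response genes were lower in samples labelled FoxO6. Of 43 measured, 10 fell, 1 rose and 32 did not pass, with 13 lower and 2 higher when adjusted over the list alone. Trim30 fell by 0.12 (SE 0.02, adjusted p = 7.83e-04) and Ifi35 by 0.15 (SE 0.03, adjusted p = 0.00141), next to Ccl5, while Usp18, a protease that removes ISG15, rose by 0.18 (SE 0.04, adjusted p = 0.00211). The list median was -0.06 with an adjusted p of 2.98e-04, or adjusted p = 0.0038 with an estimated correlation.

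Among cell cycle inhibitors and p53 targets, 5 of 29 fell, 2 rose and 22 did not pass; adjusted over the list alone 8 fell and 2 rose. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, fell by 0.25 (SE 0.06, adjusted p = 0.00413), Ccng1 by 0.26 and Mdm2 by 0.17, and Gtse1, a gene of late cell cycle, rose by 0.23. The list median was -0.05 (adjusted p = 0.0099, and adjusted p = 0.0135 with an estimated correlation). In the autophagy and lysosome list 7 of 29 fell, 1 rose and 21 did not pass, with 8 lower and 1 higher adjusted over the list alone. Bnip3l, a mitophagy receptor, fell by 0.29 (SE 0.04, adjusted p = 5.82e-05), Map1lc3b by 0.31 and Map1lc3a by 0.20, and Ulk1, the kinase that starts autophagy, rose by 0.28. Its median was -0.07 (adjusted p = 0.0099, and adjusted p = 0.0195 with an estimated correlation).

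Immediate early and cAMP response genes included 7 that rose, 0 that fell and 23 that did not pass, with 8 higher and 1 lower adjusted over the list alone. Egr1, a serum-induced transcription factor, rose by 0.37 (SE 0.08, adjusted p = 0.00176), Fos by 0.18, Myc by 0.18 and the phosphatase gene Dusp4 by 0.14. The list median was 0.04 (adjusted p = 0.0333, and adjusted p = 0.0363 with an estimated correlation), and under median centring it was 0.02 with adjusted p = 0.733, 1 of 5 settings of 44 in which it did not pass. In the list for unfolded protein and integrated stress 4 of 36 rose, 2 fell and 30 did not pass, as when adjusted over the list alone. Psat1 and Phgdh, enzymes of serine synthesis, each rose by 0.30 and Mthfd2, of mitochondrial folate metabolism, by 0.39, while Ddit3, the stress transcription factor CHOP, fell by 0.30. The median of 0.03 (adjusted p = 0.0498, and adjusted p = 0.0363 with an estimated correlation) turned to -0.01 under median centring. In 19 further settings of 44 it kept its sign but the list did not pass.

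Of 32 cholesterol and fatty acid synthesis genes, Idi1, an isoprenoid isomerase, rose by 0.40 (SE 0.06, adjusted p = 5.21e-05) and Stard4, a sterol carrier, by 0.26 (SE 0.06, adjusted p = 0.00254), 0 fell and 30 did not pass. These 2 were also the count adjusted over the list alone. Tested over all probes, 1 of 2 Idi1 probes and 1 of 3 Stard4 probes passed. The list median of 0.06 passed at adjusted p = 0.0237 but not with an estimated correlation (adjusted p = 0.12 with an estimated correlation), and it was -0.00 under median centring.

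FoxO targets moved both ways. Of 52 measured, 6 rose, 9 fell and 37 did not pass, and adjusted over the list alone 7 rose and 13 fell. The matricellular genes Ctgf and Cyr61 rose by 0.33 (SE 0.04, adjusted p = 1.25e-05) and 0.31 (SE 0.05, adjusted p = 1.29e-04), whereas Tnfsf10, the death ligand TRAIL, fell by 0.10 (SE 0.01, adjusted p = 8.23e-06), next to Txnip. As a list they did not pass (median -0.04, adjusted p = 0.178), although under median centring they did at a median of -0.07 (adjusted p = 0.0428). In PI3K and insulin signalling 5 of 29 rose and 3 fell, or 6 and 4 adjusted over the list alone. Igf1r, the IGF receptor, rose by 0.35 (SE 0.05, adjusted p = 4.38e-05) and Mtor by 0.22, and Igfbp4, an IGF-binding protein, fell by 0.35; the list gave adjusted p = 0.524.

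In the NF-kB list Birc3, an inhibitor of apoptosis, fell by 0.23 (SE 0.05, adjusted p = 0.00558), with 3 of 33 higher and 6 lower, or 3 and 7 adjusted over the list alone (list median -0.03, adjusted p = 0.058, past the threshold in 6 of 44 settings). Of 31 contractile and TGF-beta genes 5 rose and 1 fell, or 7 and 2 adjusted over the list alone, among them Id1, an inhibitor of bHLH factors, which rose by 0.40 (SE 0.06, adjusted p = 1.2e-04); the list did not pass (median 0.02, adjusted p = 0.0523), but did in 18 of 44 settings, with adjusted p as low as 0.0229. Extracellular matrix genes split, with 4 of 39 higher and 3 lower, or 7 and 4 adjusted over the list alone. Postn, periostin, fell by 0.39 (SE 0.07, adjusted p = 7.28e-04) and the proteoglycan gene Bgn by 0.38, while Col5a1 rose by 0.17 and Col12a1 by 0.19 (list adjusted p = 0.957). Among 20 genes of mesenchymal identity 3 rose and 2 fell, or 4 and 3 adjusted over the list alone, with Cdh2, N-cadherin, at 0.31 (SE 0.03, adjusted p = 2.92e-07) and Cd44 at 0.21 (list adjusted p = 0.941).

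Heat shock and oxidative stress genes held 3 of 34 higher and 4 lower, or 8 and 7 adjusted over the list alone. Nqo1, a quinone reductase, rose by 0.20 (SE 0.04, adjusted p = 0.00112) and the inducible chaperone gene Hspa1b fell by 0.16 (SE 0.04, adjusted p = 0.00542); the list gave adjusted p = 0.979. In glycolysis and hypoxia 1 of 29 rose and 4 fell, or 2 and 5 adjusted over the list alone, with Ndrg1 lower by -0.15 and Gapdh higher by 0.11 (list adjusted p = 0.313, but 0.0273 under median centring, which lowered it). Of 41 respiratory chain genes 2 rose and 1 fell, or 0 and 0 adjusted over the list alone (list adjusted p = 0.524). Median, mean and test differed in sign for the core clock, heat shock, matrix, mesenchymal and macrophage lists, none of which passed.

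Markers of other cell types moved little. Of 13 adipocyte markers Dgat2, which makes triglyceride, fell by 0.17 (SE 0.04, adjusted p = 0.012), also when adjusted over the list alone (list adjusted p = 0.36). Of 14 epithelial and endothelial markers Emcn fell by 0.05 (SE 0.02, adjusted p = 0.0479), a call lost in 26 of 43 settings, and 0 passed adjusted over the list alone (list adjusted p = 0.345). In limma, 0 of 13 myogenic markers (adjusted p = 0.711 for the list), 0 of 13 macrophage and leukocyte markers (adjusted p = 0.957) and 0 of 10 neural markers (adjusted p = 0.36) passed, over all genes or adjusted over the list alone.

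For the question raised by the series title, Clock itself did not differ on its brightest probe, at 0.03 (SE 0.06, adjusted p = 0.874, n = 16 per vector). The other 3 Clock probes gave 0.18, 0.12 and 0.00, and tested over all probes the first of these passed (SE 0.03, adjusted p = 2.5e-04). Of 22 core clock genes, Timeless, a replication fork protein, rose by 0.26 (SE 0.04, adjusted p = 3.22e-05) and Csnk1e, the casein kinase that phosphorylates PER proteins, by 0.20 (SE 0.05, adjusted p = 0.00364), 0 fell and 20 did not pass. Adjusted over the list alone 4 were higher and 3 lower. Arntl, the partner of CLOCK, gave -0.11 (adjusted p = 0.0509), Cry1 0.11 (adjusted p = 0.0675), Nfil3 -0.23 (adjusted p = 0.0661), Rora -0.15 (adjusted p = 0.0603) and Per1 0.13 (adjusted p = 0.0922). The others, Npas2, Per2, Per3, Cry2, Nr1d1, Nr1d2, Dbp, Tef, Hlf, Bhlhe40, Bhlhe41, Gm129 and Csnk1d, had adjusted p of 0.406 or more. Rorb was not well above background on most arrays, with 8 of 32 above it, so no fold is given. The core clock list gave adjusted p = 0.941, and clock-controlled output gave adjusted p = 0.609 with 3 of 27 higher and 2 lower, or 4 and 3 adjusted over the list alone. Of the latter Fkbp5, a steroid receptor co-chaperone, rose by 0.19 (SE 0.03, adjusted p = 7.97e-05), Ltbp1 by 0.23 and the kinase gene Wee1 by 0.13, and Hsd17b11 fell by 0.24.

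At 24 h Retnla was 1.25 higher in samples labelled FoxO6 (SE 0.08, adjusted p = 5.42e-10, n = 4 per group) and the mitochondrial chaperonin gene Hspe1 0.72 higher (SE 0.14, adjusted p = 0.0166). Nrm was lower at -0.78 (SE 0.09, adjusted p = 2.62e-05) and Hspb9 at -0.57 (SE 0.08, adjusted p = 7.17e-04). In all 72 tests were higher and 41 lower, 113 together, with 2679 at an unadjusted p under 0.05. At 30 h Retnla was 1.12 higher (SE 0.08, adjusted p = 6.93e-09) and Trim59 0.73 higher (SE 0.10, adjusted p = 3.46e-04), while Nrm (-0.88, SE 0.09, adjusted p = 1.68e-06) and Sdk2 (-0.72, SE 0.17, adjusted p = 0.0348) were lower. Here 226 were higher and 116 lower, 342 in all, with 2889 unadjusted. The 24 h call of Hspe1 was lost in 6 of 44 settings and the 30 h call of Sdk2 in 9.

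At 36 h Exo1 rose by 0.80 (SE 0.10, adjusted p = 1.12e-04), Rrm2 by 0.77 (SE 0.12, adjusted p = 0.00165) and Ranbp1, a regulator of nuclear transport, by 0.76 (SE 0.17, adjusted p = 0.0326). The potassium channel gene Kcnt1 fell by 0.65 (SE 0.15, adjusted p = 0.0321), Prl2c3, a proliferin, by 0.65 (SE 0.12, adjusted p = 0.00843) and Lcn2 by 0.64 (SE 0.15, adjusted p = 0.0362). There were 142 higher and 75 lower, 217 in all, with 2553 unadjusted. At 42 h Retnla rose by 0.77 (SE 0.08, adjusted p = 1.43e-05) and Ppbp by 0.73 (SE 0.12, adjusted p = 0.00386). C3 fell by 1.19 (SE 0.26, adjusted p = 0.0226), Sdk2 by 0.77 (SE 0.17, adjusted p = 0.0292, with 1 of 4 FoxO6 arrays well below the others) and Ccl5 by 0.60 (SE 0.13, adjusted p = 0.0292). There 169 were higher and 55 lower, 224 in all, with 2549 unadjusted. Over 44 settings the 36 h calls of Lcn2, Kcnt1 and Ranbp1 were lost in 10, 9 and 8, and the 42 h calls of Ccl5, Sdk2 and C3 in 8, 7 and 6.

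Probes without a symbol were also among the 3 largest at single times, such as MMAB036319 at 0.90 (SE 0.20, adjusted p = 0.0281) at 42 h and MMAB035255 at -0.84 (SE 0.16, adjusted p = 0.00976) at 24 h. Differences at any pair of times, which share no arrays, correlated at 0.393 to 0.442 across genes, which are not independent replicates. Of tests past the threshold at 24 h and at 30 h, 42 were higher and 21 lower at both, against 0.669 and 0.196 for independent lists, and 0 went opposite ways. The times share 1 estimate of spread per gene, so independent lists understate the overlap that could arise without shared changes. With median centring 15 passed at 24 h (12 higher, 3 lower), 20 at 30 h (15 higher, 5 lower), 117 at 36 h (24 higher, 93 lower) and 6 at 42 h (6 higher, 0 lower). In fits on the arrays of 1 time alone 4, 83, 3 and 3 passed at the 4 times in order.

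The difference between vectors was tested for change over time with the interaction of vector and time, and 1 of 24308 tests passed in limma, with 991 at an unadjusted p under 0.05. It was MMAB030852, a probe without a symbol (adjusted p = 0.00668), for which the difference was 0.17 at 24 h, -0.06 at 30 h, 0.25 at 36 h and -0.15 at 42 h. With median centring 0 passed, and this single call is not taken as established. Neither C3 nor Retnla passed, although their differences ranged from -0.04 to -1.19 and from 0.74 to 1.25 over the times. Among core clock genes the lowest interaction p adjusted over the list alone was 0.851, for Arntl. In clock-controlled output Alas1, the first enzyme of heme synthesis, had adjusted p = 0.0101 over the list alone and adjusted p = 0.579 over all genes.

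In empty vector cells the secreted chaperone gene Clu rose most between 24 and 42 h, by 1.69 (SE 0.09, adjusted p = 6.78e-11, n = 4 per group), from -1.09 ± 0.12 to 0.60 ± 0.14 (SD, n = 4 each). C3 rose by 1.42 (SE 0.26, adjusted p = 0.00523), Cyp2f2 by 1.33, Dcn, decorin, by 1.33, Ly6a by 1.25, Agt, angiotensinogen, by 1.24, Ly6c1 by 1.19 and Cdo1, a cysteine dioxygenase, by 1.14. Id1 fell by 1.16 (SE 0.13, adjusted p = 6.04e-06) and Cdca3, a trigger of mitotic entry, by 1.15 (SE 0.15, adjusted p = 5.22e-05). In the F-test for time C3 and Dcn each lost their call in 1 of 44 settings (adjusted p = 0.0722 and 0.923). Tested over all probes, 1 of 2 probes of each passed. In all 1104 tests passed for time, with 4121 unadjusted. Of these 302 rose throughout, 294 fell throughout, 143 were lowest at 30 or 36 h, 189 highest then, and 176 followed another course. With median centring 288 passed, without a dye term 515, and in a fit on the empty vector arrays alone 647.

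Clock genes changed over time in empty vector cells. Tef, a PAR bZIP factor under clock control, fell by 1.12 from 24 to 36 h (SE 0.08, adjusted p = 1.78e-08, n = 4 per group). Cry1, a repressor of CLOCK and BMAL1, fell by 0.85 (SE 0.08, adjusted p = 6.38e-07). Nr1d2, the nuclear receptor REV-ERB beta, fell by 0.59 from 24 to 36 h (SE 0.10, adjusted p = 0.00144) and rose by 1.01 from 30 to 42 h (SE 0.10, adjusted p = 2.33e-06). Arntl rose by 0.38 from 24 to 36 h (SE 0.07, adjusted p = 0.00323). Smaller falls from 24 to 36 h were seen for Cry2 at -0.31, Bhlhe40 at -0.25, Per3 at -0.22 and Gm129 at -0.15. Only Tef and Nr1d2 passed the test for time in all 44 settings. The call was lost in 14 for Bhlhe40, 6 for Gm129, 3 for Per3, 2 for Cry2, 1 for Arntl (adjusted p = 0.0997, median centring) and 1 for Cry1 (adjusted p = 0.564, without a dye term). Together 8 of 22 core clock genes passed the test for time, also when adjusted over the list alone; 7 of these were lowest at 30 or 36 h and Arntl was highest then.

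The same test in samples labelled FoxO6 passed for 1180 tests (4049 unadjusted) and 7 of 22 core clock genes, or 9 adjusted over the list alone; 6 of them were shared with empty vector cells. From 24 to 36 h Tef fell by 1.03 (SE 0.08), Cry1 by 0.84 (SE 0.08) and Nr1d2 by 0.77 (SE 0.10), and Arntl rose by 0.36 (SE 0.07). Timeless passed in FoxO6 samples, with -0.31 from 24 to 42 h (adjusted p = 0.011), and its interaction did not pass. Over all genes 590 passed for time in both vectors against 53.6 for independent lists, and changes from 24 to 42 h correlated at 0.691 across genes. Both tests share 1 estimate of spread per gene, so some overlap beyond 53.6 can arise without a shared time course. With median centring 373 passed in FoxO6 samples and without a dye term 503.

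**Figure D3:**
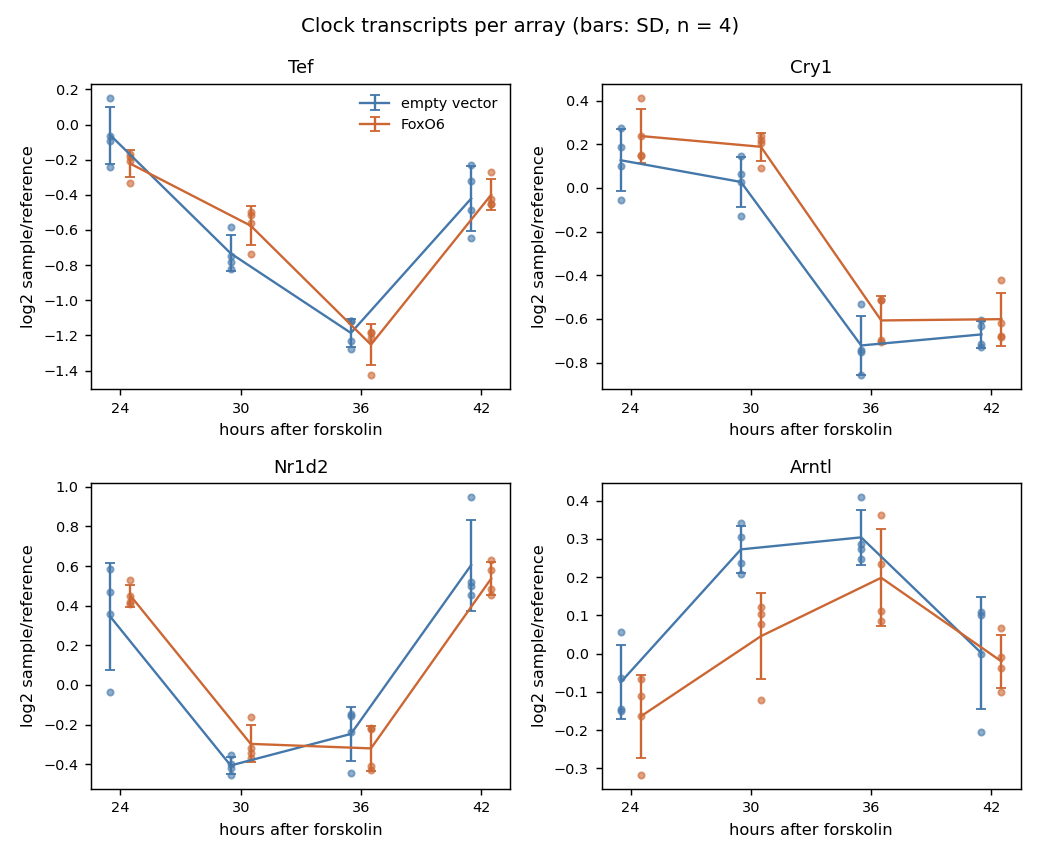
Log2 sample over reference of Tef, Cry1, Nr1d2 and Arntl on each array against hours after forskolin, for empty vector (blue) and FoxO6 (orange); points are arrays, lines join group means and bars are SD (n = 4). Tef falls from -0.06 to -1.19 between 24 and 36 h in empty vector cells and from -0.22 to -1.25 with FoxO6.

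Probes of some clock genes differed. The brightest Per2 probe gave 0.07 from 24 to 36 h in empty vector cells, while the dimmer gave -0.38 (SE 0.05, adjusted p = 1.52e-04 over all probes). Of 3 Nr1d1 probes the dimmest passed for time (adjusted p = 1.67e-06 over all probes) and the brightest did not. A pair of dimmer Rora probes gave 0.44 and 0.47 from 24 to 42 h, against -0.21 on the brightest, and the dimmer Timeless probe fell by 0.30. The Clock probe that differed between vectors also passed for time (-0.22 from 24 to 42 h, SE 0.06, adjusted p = 0.0438 over all probes), as did the dimmer of the Foxo1 probes (0.22, SE 0.08, adjusted p = 0.027). Dimmer probes of Arntl and Cry2 did not pass for time, nor did the dimmer Csnk1e probe differ between vectors (0.01, SE 0.04). All 4 Tef probes and both Cry1 probes passed for time. For the mean difference between vectors, probes of Aif1, Arntl, Col1a1, Csf1r, Csnk1d, Hmgcs1, Ltbp1, Nrf1, Rora, Syt1 and Top2a passed in the direction opposite to the brightest. Only 1 of 2 probes passed for this difference for Bgn, Birc3, Bnip3l, Col5a1, Dusp4, Pole, Postn, Trim30 and Ulk1, tested over all probes. For Cd44 and Cdh2 it was 1 of 3.

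Among gene lists over time in empty vector cells, mitosis genes fell from 24 to 36 h (32 of 39 lower, 0 higher, 37 adjusted over the list alone, median -0.53, adjusted p = 2.05e-54), and replication genes fell likewise (17 of 39 lower, 0 higher, 28 adjusted over the list alone, median -0.36, adjusted p = 6.19e-30). Both fell again from 30 to 42 h, with 18 mitosis genes and 7 replication genes lower, 0 higher, and medians of -0.39 (adjusted p = 1.35e-39) and -0.25 (adjusted p = 1.85e-19). Aurka fell by 0.59 and Kif4 by 0.51 in that interval. With an estimated correlation camera gave mitosis genes adjusted p = 2.17e-11 for 24 to 36 h and 5.72e-10 for 30 to 42 h. For replication genes it gave adjusted p = 1.83e-06 and 5.5e-05. Core clock genes were lower at 36 than at 24 h (7 lower, 1 higher, the same numbers adjusted over the list alone, median -0.10, adjusted p = 3.4e-05). Interferon genes rose, with 5 of 43 higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 4.73e-05); Ccl5 rose by 0.81, the exonuclease gene Isg20 by 0.41 and Igtp, an interferon-induced GTPase, by 0.39.

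FoxO targets were higher at 36 than at 24 h, with 2 of 52 higher and 0 lower (2 and 1 adjusted over the list alone, adjusted p = 0.0318): Gabarapl1, an ATG8 protein of autophagy, rose by 0.59 (SE 0.12) and Sepp1, selenoprotein P, by 0.50 (SE 0.13, lost in 9 of 44 settings). From 30 to 42 h the list rose again (median 0.11, adjusted p = 0.00363), with Sesn3 at 0.32 and Fbxo32, a ubiquitin ligase of atrophy, at 0.16. The list for unfolded protein rose from 30 to 42 h (median 0.18, adjusted p = 9.05e-06), with Xbp1, a transcription factor of that response, at 0.44 (SE 0.09, adjusted p = 0.0134) and Pdia4 at 0.36 (SE 0.09, adjusted p = 0.0467, lost in 22 of 44 settings). Interferon genes (adjusted p = 5.92e-04) and mesenchymal genes (adjusted p = 0.0253) rose in that interval too. All of these lists passed with an estimated correlation as well. Clock-controlled output fell from 24 to 36 h (adjusted p = 0.015) and rose from 30 to 42 h (adjusted p = 0.0145), but adjusted p = 0.06 and adjusted p = 0.0558 with an estimated correlation. NF-kB genes rose in both intervals (adjusted p = 0.015 and 0.0339), but adjusted p = 0.0703 and adjusted p = 0.13 with an estimated correlation. Matrix genes rose from 30 to 42 h (adjusted p = 0.0167), but adjusted p = 0.29 with an estimated correlation.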

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

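The comparison of quality-control probes and the look at how the splits mixed the labels were chosen after the results were seen; the others below were fixed beforehand.

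Within groups of 4 arrays, 18 of 416 groups of values, from 50 named genes and 2 measures per array, held an array that stood apart, where chance at 1 in 20 gives 20.8. All 18 were of genes, and each is given as the array minus the mean of the other 3 of its group. In empty vector cells at 24 h replicate a lay at -0.138 for Sdk2 and 0.0944 for Npas2. At 30 h replicate a lay at 0.114 for Rrm2. At 36 h replicate a lay at -0.221 for Uhrf1 and d at 0.432 for Foxo1. At 42 h replicate d lay at 0.771 for Npc2, c at 0.456 for Nr1d2, b at 0.574 for Nfil3 and a at 0.257 for Bhlhe41. With FoxO6 at 24 h replicate c lay at 0.214 for Retnla, 0.49 for Shcbp1 and -0.549 for Lcn2, and d at -0.295 for Dbp. With FoxO6 at 36 h replicate d lay at 0.502 for Ptgs2 and a at -0.231 for Tef. With FoxO6 at 42 h replicate d lay at -0.652 for Sdk2 and -0.0889 for Gm129, and c at 0.174 for Tef.

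The interaction test of limma passed for MMAB030852, a probe without a symbol (adjusted p = 0.00668), but 0 tests passed with median centring, and chance cannot be excluded for this count of 1, as 7 of 100 splits of the arrays, the real one included, gave at least as many. Among control spots left out of the comparisons, 82 of 245 probes of the class named QCMM passed for the mean difference between vectors, or 33.5%, of which 35 were higher. Their differences ran from -0.382 to 0.457, with 9 spots per probe. In the main comparison, where each probe had 1 spot, 2554 of 24308 tests passed. In the class named QCAA 13 of 93 passed. What these probes detect is not given in the sources used here.

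Other splits of the arrays into groups of the same sizes were refitted with limma. For the mean over times 1 of 100 drawn splits, the real one, gave as many as 2554, the highest other giving 1. Chance labelling of these samples was thus an unlikely source of this count. The real split was also alone in giving its count at 24 h (1 of 35 splits, 113 against 1), 30 h (342 against 2), 36 h (217 against 1) and 42 h (224 against 24). With 35 splits, 1 in 35 is the smallest share possible. It was alone too for time in empty vector cells (1104 against 275) and FoxO6 samples (1180 against 92, 1 of 100 each). Splits of these samples cannot exclude a difference between cultures or transfections that follows the vector. For the interaction, with 1 real call, the highest other was 45. That split kept the FoxO6 label on 4 of 4 arrays at 36 h and on 0 of 4 at 42 h, so the structure it picked up includes the difference between vectors, which enters the interaction by construction.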

How the results depend on the processing

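Leaving out a whole time, or the pair of arrays with the largest residuals, was chosen after the data were seen. For the mean difference, then at 24, 30, 36 and 42 h, for the interaction, and for time in empty vector and FoxO6 cells, the counts were 2554, 113, 342, 217, 224, 1, 1104 and 1180. With median centring they were 1086, 15, 20, 117, 6, 0, 288 and 373; this setting leaves the trend of ratio with intensity in place, but the cause of the change was not tested. Without a dye term they were 1395, 33, 80, 56 and 39, then 515 and 503 for time; dye bias then enters the spread by construction. With every probe on its own, which tests more features, they were 5607, 387, 1100, 397, 664, 4, 1919 and 2115. On the arrays of 1 time 4, 83, 3 and 3 passed, and 647 for time on the empty vector arrays; fewer arrays leave fewer degrees of freedom. The interaction gave 3 without background correction and 4 from the series table; the cause was not tested. Without the pair of arrays 134 passed at 36 h. The mean difference gave 1339 without the 30 h arrays and 1650 without the 36 h arrays, with fewer samples in each. Apart from leaving out single arrays, the other settings left these counts within 1.5 times, and quantile scaling of mean intensities leaves log ratios as they were.

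With the replicate letter as a replicate block the counts were 2533, 111, 339, 210, 205, 1, 1123 and 1196. Letters a and c carried Cy3 and b and d Cy5 in every group. This block thus also takes up the dye, and counts near the main ones are partly built in. The letters gave no clear sign of pairing. Correlations of residuals between vectors lay between -0.0844 and 0.149, and 1 of 16 was over 0.1. Of 16 empty vector arrays, 4 correlated best with their own letter.

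Leaving out 1 array at a time gave 2246 to 2574 for the mean difference, 43 to 138 at 24 h, 137 to 397 at 30 h, 92 to 264 at 36 h, 101 to 254 at 42 h, 1 to 4 for the interaction, 833 to 1134 and 864 to 1334 for time in empty vector and FoxO6 cells, and 6 to 10 lists. Counts moved over 1.5 times at 24 h without empty vector a (66) and FoxO6 b (70), c (43) or d (58); at 30 h without empty vector b (173), c (213) or d (181) and FoxO6 b (189) or c (137); at 36 h without empty vector c (92) or d (128) and FoxO6 b (135), c (100) or d (131). At 42 h they did so without empty vector a (101), b (132), c (111) or d (116) and FoxO6 a (123), c (110) or d (110). The interaction gave 4 without FoxO6 36 h b, and 2 without empty vector 30 h b or d, 42 h a, FoxO6 24 h a or 42 h b. In each case 1 array fewer stands in the comparison.

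Under median centring the list medians for cholesterol synthesis (-0.003365) and unfolded protein (-0.01448) changed sign, while DNA replication (0.22) and mitosis (0.24) stayed past the threshold. Of 8 lists called, 5 passed in every alternative and 3 did not; of 200 called values of named genes 82 did and 118 did not, and 0 changed sign. Dim probes, whose ratios shrink toward 0 near background, limit what these arrays show. The list tests over time were rerun with an estimated correlation alone, and a slide or scan batch was not run.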

Other observations

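The tests on the cell cycle lists and on the Foxo6 probe, and a comparison with dimmer probes, were chosen after the results were seen.

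At each of the 4 times taken singly, 23 tests passed in limma, 19 higher and 4 lower in samples labelled FoxO6. They were picked by this overlap after their values were seen. Besides Rrm2, Tk1, Exo1, Cdc6 and Retnla, those with a gene name included E2f7, a repressor among the E2F factors, with a mean difference of 0.48, Rad18, a ubiquitin ligase of DNA damage tolerance, at 0.44, Pkmyt1, a kinase that restrains CDK1, at 0.40, Ep300, a histone acetyltransferase, at 0.38, Chtf18, a clamp loader subunit, at 0.36, Clspn, claspin, at 0.35 and the formin gene Diap3 at 0.31. Srgn, the proteoglycan serglycin, stood at 0.45. Fam105a at -0.43 and P4ha3, a prolyl hydroxylase of collagen, at -0.31 were lower.

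The 78 cell cycle genes of both lists had a median difference of 0.27 in samples labelled FoxO6, which lay 0.247 above the upper limit of 10000 random lists matched on intensity, which argues against a trend with brightness left by the normalization. A delay of the whole time course, 9.75 h to account for these lists, would shift 8 clock genes too, but the slope of observed on predicted shifts was 0.0443 (interval -0.0355 to 0.143), which argues against it. From 24 to 42 h replication genes had median changes of -0.47 in empty vector cells and -0.48 with FoxO6, and mitosis genes of -0.70 and -0.48. The mitosis list mean went from 0.13 ± 0.03 to -0.53 ± 0.03 in empty vector cells and from 0.27 ± 0.01 to -0.20 ± 0.02 with FoxO6 (SD, n = 4 each). The mitosis list thus fell less with FoxO6, beyond the spread between arrays, and the replication list did not. Of either list 0 members passed the interaction over the list alone. Adjusted over all genes, the interaction test recovered only 34% of simulated changes of 0.2. Recovery adjusted over a list alone was not simulated, and no list was tested for interaction as a whole. Genes outside the lists that changed with time in empty vector cells differed the opposite way in samples labelled FoxO6 in 68.2% of 1048, but these are not limited to growth genes, so a slower decline of growth genes alone and a lag of many genes that spares the clock cannot be told apart. FoxO6 itself, which the design names, and a difference in cell density or transfection between cultures, for which the tables hold no measure, may each give this and stay open and untested.

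The Foxo6 probe was not higher in samples labelled FoxO6. It lay above background on 16 of 16 such arrays, which argues against a probe without signal. As 79.1% to 93.4% of all probes did so on an array, this does not settle whether the probe was bright enough to show a rise. The upper limit of its change was 0.0678, so that a probe outside the sequence on the plasmid and a plasmid that was not expressed cannot be told apart while the probe's sequence is unknown here.

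For Per2, Nr1d1 and Rora the brightest probe did not change with time while dimmer probes did. Compression of bright signals was predicted to lower the share of bright genes that change with time. That share was instead 0.888 percentage points higher in the brightest class (6.44%) than in the middle (5.55%). It also depends on which genes change and on the spread, with a median residual SD of 0.166 against 0.105. The share therefore cannot exclude compression. Over 1050 genes with several probes, at least 1 of which passed, the brightest passed in 47.1%, under the bound of 50% set beforehand for bright probes being usually the flatter. That bound cannot decide, because these genes were picked for at least 1 call and had 2152 dimmer probes, so calls spread over several probes. In a comparison added after that value was seen, 35.4% of the dimmer probes passed, a smaller share than of the brightest. Genes with many probes weigh more in the pooled dimmer share than in that of the brightest, so this comparison cannot decide either. Per2, Nr1d1 and Rora stay unexplained. No biological explanation was tested, and which transcripts each probe detects is not given in the sources used here.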
